A study of Homo sapiens with 18 samples.

How the data were processed

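Gene expression was measured by RNA sequencing in 18 libraries of the 16D cell line, in 6 groups of 3: DMSO, and 10 µM enzalutamide for 24, 48, 96 or 144 h or for more than 2 months. Per the labels' protocols, libraries were poly(A)-selected and strand-specific and were read as single reads of 50 bp. The submitters' processing notes name STAR, RSEM and Partek and the builds hg38 and GRCh38, without the role, order or version of any of them. The deposited values are TPM per gene, made by the authors, and every library sums to nearly the same total. The authors' 3 columns of mean TPM equalled the mean of 3 libraries for all genes within 0.01 TPM. The deposited fold columns, ratios of the authors' mean columns without an error, were not used. No read totals or counts were held, so the depth and the counting error of each library are unknown. Gene positions and gene types were taken from GENCODE release 29 (GRCh38), to which 58516 gene identifiers matched, and 71 symbols occurred more than once.

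Values were transformed to log2(TPM + 1), and genes with TPM of at least 1 in at least 3 libraries were kept, which left 16169 genes. Group differences were tested with limma 3.58.1 in R 4.3.3, with 1 linear model of all 18 libraries and 6 group means, moderated with a trend of the variance on mean expression. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg within each of 7 comparisons: each treated group against DMSO, 144 h against 24 h, and long-term against 144 h. Genes with an adjusted p under 0.05 are called changed. All comparisons with DMSO share the same 3 control libraries. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

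There were 34 gene lists, of which 29 held at least 5 tested genes and were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists. Genes too low to pass the filter left 7 of 25 neuroendocrine markers, 8 of 18 steroid synthesis genes, 9 of 16 EMT genes and 20 of 30 interferon-response genes. The same lists were tested with a correlation estimated for each list and with limma's fry. Camera compares a list with the other genes, while fry asks whether a list's own genes moved one way and makes no such comparison. With an estimated correlation the androgen-induced list kept its call at 24, 48, 96 and 144 h against DMSO and the glucocorticoid-response list at 48, 96 and 144 h, and no other list kept one in any of the 7 comparisons. No 2 lists shared more than 1 gene, and 11 pairs shared 1, such as FKBP5 in the androgen-induced and glucocorticoid-response lists and MYC in the immediate early and MYC target lists. For each list the number of called members is given over all genes tested and adjusted over the list alone.

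The samples, lists, comparisons, tests and the rule for naming genes were chosen before the data were examined, as were all alternatives except the covariate described in the last paragraph. Named are KLK3, KLK2, TMPRSS2, FKBP5, MYC, NR3C1, DNM1L, HK2, MKI67 and CDKN1A in each comparison. Some genes that the choices described in this paragraph would name are not reported here. Also named are the 10 genes with the largest change in each direction at 24 h, 144 h and long-term against DMSO, and the 5 in the other comparisons. These genes had an adjusted p under 0.05, no overlap between the libraries of both groups, a mean TPM of at least 5 in the higher group, and a symbol that is not a clone name, a pseudogene copy or Y-linked. From each list described, up to 4 called members with the smallest adjusted p were eligible. After the results were seen, the small RNA genes MIR6727 and SNORD5 (24 h) and MIR6835, MIR671 and SNORA50C (48 h) were left out of those comparisons, because leaving out single libraries ended their calls. For the same reason list members and lists whose call ended without a single library or under another scaling were not described there, except where that is stated, and 1 to 4 of the eligible members are given per list.

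The test was checked on simulated data made from the real means and spread. In a simulated 24 h against DMSO comparison of 15580 genes, 97 of 100 genes changed by 1 on the log2 scale were recovered, as were 63 of 100 genes changed by 0.5 and 15 of 40 genes of a list raised by 0.3. That comparison had 186 calls, 11 of them of unchanged genes, and the simulated 48 h comparison, where nothing was changed, had 1 call. The changed genes and those of the list were drawn only from genes with means above about 5 TPM. Recovery of lower genes was therefore not tested. Simulated genes varied independently, so noise shared between genes was not covered.

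Alternatives to the main choices were a pseudocount of 0.1, a filter of 5 TPM, no filter, median-of-ratios scaling, quantile normalization, rescaling without the 37 mitochondrially encoded genes, a fit of only the libraries of both groups compared, no variance trend, the replicate number as a block, and leaving out each library in turn. After seeing that the mitochondrial share of TPM varied within a group, that share was added as a covariate in a further alternative.

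To look for chromosome regions, the 10577 tested genes on chromosomes 1 to 22 and X with a mean of at least 5 TPM over the groups were ordered by position. They were divided into 343 windows of 30 genes, leaving out the incomplete last window of each chromosome. The median log2 fold change of a window, centred on the median of these genes, was set against the largest of 95% of permutations of the gene order. In 100 simulations both shifted windows were found in 100, and 5 of 100 simulations without a shift gave a window. The simulated genes varied independently, so noise shared by neighbouring genes was not covered. Of 18 real contrasts of 1 library with the others of its group, 13 gave a window, so the simulated rate cannot be carried over to them.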

Results

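RNA was measured in 16D, an established human castration-resistant prostate cancer cell line, grown in RPMI with 10% FBS and given either the solvent DMSO or 10 µM enzalutamide, an antiandrogen drug. There were 6 groups of 3 libraries each, 18 in all: DMSO, enzalutamide for 24, 48, 96 or 144 h, and enzalutamide for more than 2 months, called long-term here. The deposited values are TPM, the relative abundance of each gene's transcripts scaled to the same total in every library, and 16169 genes were tested. TPM keep no read totals, so the depth of each library is unknown, and no counting interval can be given. Group levels are mean TPM ± SD and log2 fold changes are given ± standard error, on the scale of log2(TPM + 1), with n = 3 libraries per group throughout. That scale understates the change of genes with low TPM. Signed values without a unit are log2 fold changes of the comparison described. Adjusted p-values are from limma's moderated test for genes and from limma's camera test for gene lists. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure the spread between these libraries only. The single DMSO group has no stated harvest time, and there is no DMSO group for each treatment time. Time in culture and drug therefore cannot be separated in any comparison.

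Log2 values of libraries within a group correlated across genes with Pearson's r of 0.983 to 0.990, and the first and second principal components held 39.7% and 19.6% of the variance. No leukocyte marker exceeded 0.83 TPM in any library, and 1 of 9 fibroblast markers passed the expression filter, COL1A1, a collagen chain gene at 14.5 TPM in DMSO. Mitochondrially encoded transcripts took 19.4 ± 1.49% of TPM in DMSO, 19.8 ± 2.34% at 144 h and 26.4 ± 3.91% in the long-term libraries. Within the 96 h group that share ran from 15.1% to 24.0%. Replicate 1, 2 or 3 of a group was not stated to match the same number of another group. The expression of NR3C1, the glucocorticoid receptor gene, was too low to be tested, at 0.0367 TPM in DMSO and 0.503 TPM in the long-term group.

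**Figure D1:**
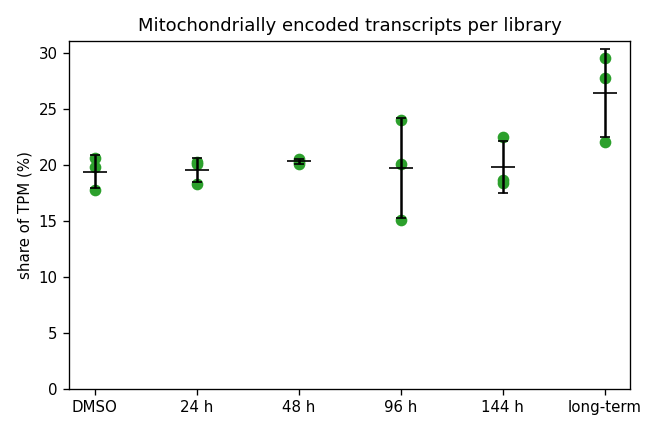
Share of TPM, in percent, from the mitochondrially encoded genes in each group. Points are libraries, horizontal bars are means and error bars are SD (n = 3); the long-term mean was 26.4% and the DMSO mean 19.4%.

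After 24 h of enzalutamide, the classical androgen-induced genes of prostate cells were lower than in DMSO. KLK3, which encodes prostate-specific antigen (ENSG00000142515, chromosome 19, 50854915 to 50860764, GRCh38), fell from 1021 ± 28.0 to 313 ± 7.22 TPM, a log2 fold change of -1.70 ± 0.06 (adjusted p = 1.71e-11). KLK2, a kallikrein gene next to KLK3 (ENSG00000167751, chromosome 19, 50861568 to 50880567), fell from 151 ± 5.58 to 23.8 ± 1.06 TPM. TMPRSS2, a serine protease gene (ENSG00000184012, chromosome 21, 41464551 to 41531116), fell from 109 ± 12.7 to 32.6 ± 1.61 TPM, and FKBP5, a co-chaperone gene of steroid receptors (ENSG00000096060, chromosome 6, 35573585 to 35728583), from 87.0 ± 8.27 to 34.1 ± 1.20 TPM. KLK2 and KLK3 are similar in sequence, so the split of reads between them is uncertain.

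Of the 38 androgen-induced genes measured at 24 h, 34 fell and 1 rose, and the counts were 34 and 1 adjusted over the list alone (adjusted p = 6.92e-63, and adjusted p = 0.00333 with an estimated correlation). Examples were C1orf116 at -2.29 and SLC45A3, a prostate solute carrier gene, at -2.20. Genes repressed by androgen went the other way, with 4 of 9 members higher and 1 lower, or 5 and 2 adjusted over the list alone, and a median of 0.28 (adjusted p = 0.00389, and adjusted p = 0.381 with an estimated correlation). OPRK1, an opioid receptor gene, rose by 1.29, ACKR3, an atypical chemokine receptor gene, by 1.14 and CAMK2N1, which encodes an inhibitor of CaM kinase II, by 0.97. The largest increases included SOX9, a transcription factor gene, from 1.37 ± 0.110 to 8.07 ± 0.817 TPM, the adhesion gene CNTN5, from 1.58 ± 0.416 to 7.88 ± 1.49 TPM, CBLN2 (1.63), C5orf66 (1.53), BAMBI, a pseudoreceptor gene of the TGF-beta family (1.44), SDC4 (1.43), GASK1B (1.43), LRRN1 (1.41) and RBP5 (1.35). The largest decreases were in ST6GALNAC1, a sialyltransferase gene (-3.26), the alcohol dehydrogenase gene ADH1C (-2.99) and the cold-sensing channel gene TRPM8 (-2.87). CHRNA2 (-2.47), NNMT (-2.45) and TRGC1 (-2.22) followed.

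In the fatty acid synthesis list at 24 h there were 1 of 17 members higher and 6 lower, or 1 and 7 adjusted over the list alone (adjusted p = 8.12e-06, and adjusted p = 0.341 with an estimated correlation). ACSL3, an acyl-CoA synthetase gene, changed by -1.77 and the elongase genes ELOVL2, ELOVL7 and ELOVL5 changed by -1.94, -1.61 and -1.27. Cholesterol synthesis had 0 of 23 members higher and 5 lower, or 0 and 9 adjusted over the list alone (adjusted p = 5.45e-08, and adjusted p = 0.341 with an estimated correlation). Among glucocorticoid-response genes, 4 of 10 fell and 2 rose, against 6 and 2 adjusted over the list alone (adjusted p = 0.00179, and adjusted p = 0.248 with an estimated correlation). ZBTB16 was at -1.69 and the metallothionein gene MT2A at 0.56. Targets of ATF4, the transcription factor of the amino acid response, had 10 of 23 members higher and 0 lower, or 12 and 0 adjusted over the list alone (adjusted p = 4.43e-07, and adjusted p = 0.341 with an estimated correlation). Examples were DDIT3 (0.79), SLC7A5, an amino acid transporter gene (0.67), CHAC1 (0.57) and NUPR1 (0.43).

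At 24 h, nucleolar targets of MYC had 0 of 42 members higher and 9 lower, or 0 and 15 adjusted over the list alone (adjusted p = 3.93e-09, and adjusted p = 0.341 with an estimated correlation). NOP16 was at -0.27. DNA replication genes of S phase had 0 of 41 members higher and 6 lower, or 0 and 12 adjusted over the list alone (adjusted p = 3.23e-10, and adjusted p = 0.341 with an estimated correlation). Examples were ATAD2 (-0.54) and TYMS, thymidylate synthase (-0.29). Genes of the unfolded protein response had 0 of 22 members higher and 6 lower, or 0 and 8 adjusted over the list alone (adjusted p = 3.2e-07, and adjusted p = 0.341 with an estimated correlation). CREB3L4 was at -0.57 and MANF at -0.34. In the WNT, NOTCH and hedgehog list there were 4 of 14 members higher and 0 lower, or 5 and 0 adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.341 with an estimated correlation). Examples were LEF1 (0.96), WNT5A (0.92) and NOTCH3 (0.91). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) was at 277 ± 30.3 TPM in DMSO and 240 ± 15.2 TPM at 24 h (adjusted p = 0.414). DNM1L, HK2, MKI67 and CDKN1A had adjusted p of 0.210, 0.152, 0.846 and 0.802, so no change was called for any of these 5 genes. In all, 1321 of 16169 genes changed at 24 h, 742 higher and 579 lower, of which 155 changed by at least 1 on the log2 scale, 47 up and 108 down. Libraries of both groups did not overlap for 27.3% of genes, where chance gives 10% for 3 against 3. The camera test called 14 of 29 lists. Without DMSO replicate 1 the count of changed genes was 869. Of the calls, 56.2% were higher, against 49.2% without DMSO replicate 3 and 44.3% after median-of-ratios scaling, which raised the count to 2026. With the mitochondrial share as a covariate the count was 2292.

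After 48 h, KLK3 was at 171 ± 2.39 TPM against 1021 ± 28.0 in DMSO, a log2 fold change of -2.57 ± 0.06, and KLK2 at 11.9 ± 0.548 against 151 ± 5.58 TPM (-3.56 ± 0.09). MYC, a growth-promoting transcription factor gene, fell from 277 ± 30.3 to 187 ± 7.06 TPM (-0.56 ± 0.13, adjusted p = 0.00588) and HK2, a hexokinase gene, from 19.2 to 11.9 TPM (-0.65 ± 0.11, adjusted p = 0.000761). The largest increases included CNTN5 (2.67), MATN2, a matrilin gene (2.37), and DDC, the gene of aromatic amino acid decarboxylase (2.33), which went from 19.2 ± 1.39 to 101 ± 1.14 TPM. ST6GALNAC1 (-4.76) and ADH1C (-3.32) were again among the largest decreases. The log2 fold changes of TMPRSS2 and FKBP5 were -1.70 and -1.62. DNM1L, MKI67 and CDKN1A had no call, with adjusted p of 0.0835, 0.469 and 0.142.

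Of androgen-induced genes, 34 of 38 fell and 1 rose at 48 h, against 34 and 2 adjusted over the list alone (adjusted p = 9.87e-48, and adjusted p = 0.00620 with an estimated correlation). Glucocorticoid-response genes had 0 of 10 members higher and 7 lower, or 0 and 8 adjusted over the list alone (adjusted p = 1.35e-08, and adjusted p = 0.00620 with an estimated correlation). Examples were ZBTB16 (-1.66), the clock gene PER1 (-1.18) and MT2A (-0.48). Androgen-repressed genes had 6 of 9 members higher and 2 lower, or 6 and 2 adjusted over the list alone (adjusted p = 0.000376, and adjusted p = 0.430 with an estimated correlation). UGT2B15, a gene of androgen glucuronidation, was at 1.62 and CAMK2N1 at 1.74. UGT2B15, UGT2B17 and UGT2B11 are similar genes of 1 family that can share reads, so their separate values are uncertain. MYC nucleolar targets had 0 of 42 members higher and 22 lower, or 0 and 29 adjusted over the list alone (adjusted p = 1.62e-13, and adjusted p = 0.171 with an estimated correlation). NOP16 was at -0.46 and SRM, spermidine synthase, at -0.34. Fatty acid synthesis had 2 of 17 members higher and 8 lower, or 2 and 10 adjusted over the list alone (adjusted p = 1.42e-06, and adjusted p = 0.430 with an estimated correlation). ACSL3 was at -2.02. Cholesterol synthesis had 0 of 23 members higher and 9 lower, or 0 and 12 adjusted over the list alone (adjusted p = 1.24e-06, and adjusted p = 0.430 with an estimated correlation).

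At 48 h, antigen presentation genes had 7 of 11 members higher and 1 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.000863, and adjusted p = 0.430 with an estimated correlation). TAPBP, the tapasin gene, rose by 0.54, and HLA-B and HLA-E by 0.65 and 0.63, although reads of HLA class I genes are hard to tell apart and these values are uncertain. Immediate early genes had 2 of 12 members higher and 5 lower, or 2 and 7 adjusted over the list alone (adjusted p = 0.0216, and adjusted p = 0.501 with an estimated correlation). JUN was at -0.92, FOS at -0.75 and, in the other direction, EGR1 at 1.35. S phase genes had 0 of 41 members higher and 12 lower, or 0 and 18 adjusted over the list alone (adjusted p = 1.42e-06, and adjusted p = 0.501 with an estimated correlation). CDC6, a replication licensing gene, was at -0.41. Unfolded protein response genes had 1 of 22 members higher and 8 lower, or 1 and 12 adjusted over the list alone (adjusted p = 3.99e-06, and adjusted p = 0.430 with an estimated correlation). The chaperone gene DNAJB9 was at -1.19. Autophagy and lysosome genes had 5 of 22 members higher and 0 lower, or 6 and 0 adjusted over the list alone (adjusted p = 0.0214, and adjusted p = 0.538 with an estimated correlation). MAP1LC3B was at 0.39. Ribosomal protein genes had 11 of 50 members higher and 0 lower, or 14 and 0 adjusted over the list alone (adjusted p = 3.05e-06, and adjusted p = 0.505 with an estimated correlation). RPS19 was at 0.29. At 48 h 2823 genes changed, 1517 higher and 1306 lower, and 272 by at least 1 on the log2 scale, 122 up and 150 down. Libraries did not overlap for 39.8% of genes, where chance gives 10%, and 16 lists were called. The higher share of the calls was 53.7%, against 46.6% with median-of-ratios scaling and 49.3% without DMSO replicate 3.

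After 96 h, KLK3 was at 71.8 ± 3.88 TPM (-3.81 ± 0.06 against DMSO), KLK2 at 7.01 ± 0.322 TPM (-4.25 ± 0.09) and FKBP5 at 23.6 ± 3.09 TPM (-1.84 ± 0.10). The log2 fold change of TMPRSS2 was -1.67. DDC rose to 217 ± 24.4 TPM (3.43 ± 0.10), CNTN5 to 29.5 ± 1.70 TPM (3.58 ± 0.15) and IGFBP3, which encodes a binding protein of insulin-like growth factors, by 2.70 ± 0.07, from 13.5 ± 1.45 to 92.9 ± 1.59 TPM. MATN2 rose by 3.24, while ST6GALNAC1 (-5.89), the secretoglobin gene SCGB1A1 (-3.62) and TM4SF1 (-3.57) fell. MYC fell to 149 ± 15.2 TPM (-0.89) and HK2 to 9.53 TPM (-0.95). MKI67 and CDKN1A had no call, with adjusted p of 0.564 and 0.0582. DNM1L, a mitochondrial fission gene, was at -0.28 with adjusted p = 0.0361, which became 0.119 without DMSO replicate 1, 0.109 without DMSO replicate 2, 0.0625 without 96 h replicate 1 and 0.140 without 96 h replicate 3. It was 0.0525 with the replicate number as a block, 0.0554 in a fit of only those 6 libraries and 0.0764 without a filter.

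Androgen-induced genes had 34 of 38 lower and 2 higher at 96 h, against 34 and 2 adjusted over the list alone (adjusted p = 9.47e-39, and adjusted p = 0.0257 with an estimated correlation). Glucocorticoid-response genes had 0 of 10 members higher and 7 lower, or 0 and 7 adjusted over the list alone (adjusted p = 4.03e-06, and adjusted p = 0.0300 with an estimated correlation). KLF15 was at -0.56. Androgen-repressed genes had 6 of 9 members higher and 2 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.000384, and adjusted p = 0.309 with an estimated correlation). OPRK1 was at 1.93 and ACKR3 at 1.71. MYC nucleolar targets had 0 of 42 members higher and 33 lower, or 0 and 38 adjusted over the list alone (adjusted p = 1.57e-17, and adjusted p = 0.0827 with an estimated correlation). NOP56 was at -0.57. S phase genes had 0 of 41 members higher and 28 lower, or 0 and 32 adjusted over the list alone (adjusted p = 1.97e-12, and adjusted p = 0.307 with an estimated correlation). FEN1, a flap endonuclease gene, was at -0.64 and CDC45 at -0.46. Fatty acid synthesis had 2 of 17 members higher and 12 lower, or 2 and 12 adjusted over the list alone (adjusted p = 2.35e-07, and adjusted p = 0.307 with an estimated correlation). ELOVL2 was at -3.20. Cholesterol synthesis had 0 of 23 members higher and 13 lower, or 0 and 14 adjusted over the list alone (adjusted p = 3.61e-06, and adjusted p = 0.398 with an estimated correlation). FDPS was at -0.46.

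Of the 25 neuroendocrine markers only 7 passed the expression filter and were tested. At 96 h they had 3 of 7 members higher and 0 lower, or 3 and 0 adjusted over the list alone (adjusted p = 0.0174, and adjusted p = 0.307 with an estimated correlation), the neuronal enolase gene ENO2 rising by 1.67 and SYT4, a synaptotagmin gene, by 0.90. The WNT, NOTCH and hedgehog list had 5 of 14 members higher and 0 lower, or 5 and 0 adjusted over the list alone (adjusted p = 0.00827, and adjusted p = 0.307 with an estimated correlation). NOTCH3 was at 2.00. ATF4 targets had 3 of 23 members higher and 11 lower, or 3 and 12 adjusted over the list alone (adjusted p = 0.00239, and adjusted p = 0.439 with an estimated correlation). ASNS, asparagine synthetase, was at -0.36, TRIB3 at -0.54 and DDIT3, in the other direction, at 0.50. Immediate early genes had 2 of 12 members higher and 7 lower, or 2 and 7 adjusted over the list alone (adjusted p = 0.00803, and adjusted p = 0.406 with an estimated correlation). DUSP1, a MAP kinase phosphatase gene, was at -0.80. Antigen presentation had 7 of 11 members higher and 2 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.00229, and adjusted p = 0.307 with an estimated correlation). TAPBP was at 0.75. Unfolded protein response genes had 1 of 22 members higher and 12 lower, or 1 and 12 adjusted over the list alone (adjusted p = 0.000147, and adjusted p = 0.412 with an estimated correlation). CREB3L2 was at -0.76. Autophagy and lysosome genes had 10 of 22 members higher and 0 lower, or 10 and 1 adjusted over the list alone (adjusted p = 0.00778, and adjusted p = 0.439 with an estimated correlation). CTSB, cathepsin B, was at 0.46. Replication-dependent histone genes had 8 of 12 members higher and 0 lower, or 10 and 0 adjusted over the list alone (adjusted p = 0.00176, and adjusted p = 0.281 with an estimated correlation). HIST1H2AC was at 0.59. These transcripts mostly lack a poly(A) tail, so their level in poly(A)-selected libraries is not the full one. Mitochondrial dynamics genes had 1 of 16 members higher and 7 lower, or 1 and 9 adjusted over the list alone (adjusted p = 0.00477, and adjusted p = 0.439 with an estimated correlation). TFAM, a factor of mitochondrial DNA maintenance, was at -0.42. At 96 h 4729 genes changed, 2670 higher and 2059 lower, and 505 by at least 1 on the log2 scale, 293 up and 212 down. Libraries did not overlap for 41.1% of genes, where chance gives 10%, and 16 lists were called. The higher share of the calls was 56.5%, against 47.4% with median-of-ratios scaling, and without single libraries it ran from 49.7% (96 h replicate 1) to 64.0% (96 h replicate 3).

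After 144 h, KLK3 was at 34.2 ± 1.95 TPM against 1021 ± 28.0 in DMSO (-4.86 ± 0.06, adjusted p = 7.88e-18) and KLK2 at 4.99 ± 1.01 against 151 ± 5.58 TPM (-4.68 ± 0.09). ST6GALNAC1 fell from 132 ± 22.3 to 0.683 ± 0.142 TPM (-6.30 ± 0.15), and TMEFF2, a transmembrane gene of prostate and brain, from 183 ± 4.51 to 4.91 ± 0.586 TPM (-4.96 ± 0.09). CNTN5 rose from 1.58 ± 0.416 to 69.4 ± 12 TPM (4.77 ± 0.15), DDC from 19.2 ± 1.39 to 305 ± 16.8 TPM (3.92 ± 0.10) and IGFBP3 from 13.5 ± 1.45 to 189 ± 13.4 TPM (3.72 ± 0.07). MYC fell from 277 ± 30.3 to 133 ± 29.4 TPM (-1.07 ± 0.13, adjusted p = 4.97e-06).

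Other large increases at 144 h were in MATN2 (3.94), MAST4, a kinase gene (3.32), LRRN1 (3.23), MIR671 (3.20), DEGS2, a sphingolipid desaturase gene (3.18), the collectin gene COLEC12 (3.14) and CAMK2N1 (3.09). MIR671 is a small RNA gene whose call at 48 h ended without single libraries. No read counts were held, so few reads may underlie its values. Other large decreases were in TM4SF1 (-4.22), ELOVL2 (-3.90), ELOVL7 (-3.72), SLC45A3 (-3.56) and ADH1C (-3.50). SCGB1A1 was at 11.8 ± 1.71 TPM in DMSO and listed at 0 in all 144 h libraries. TMPRSS2 (-1.48), FKBP5 (-2.05) and HK2 (-1.34) fell as well. CDKN1A, the p21 gene, had no call (adjusted p = 0.170). MKI67, a proliferation marker, was at -0.39 with adjusted p = 0.0201, which became 0.103 without DMSO replicate 2, 0.112 without 144 h replicate 2 and 0.128 in a fit of only those 6 libraries. DNM1L was at -0.28 with adjusted p = 0.0244, which became 0.0855 without DMSO replicate 1, 0.0763 without DMSO replicate 2, 0.0688 without 144 h replicate 1, 0.0929 without 144 h replicate 2 and 0.0513 without a filter.

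**Figure D2:**
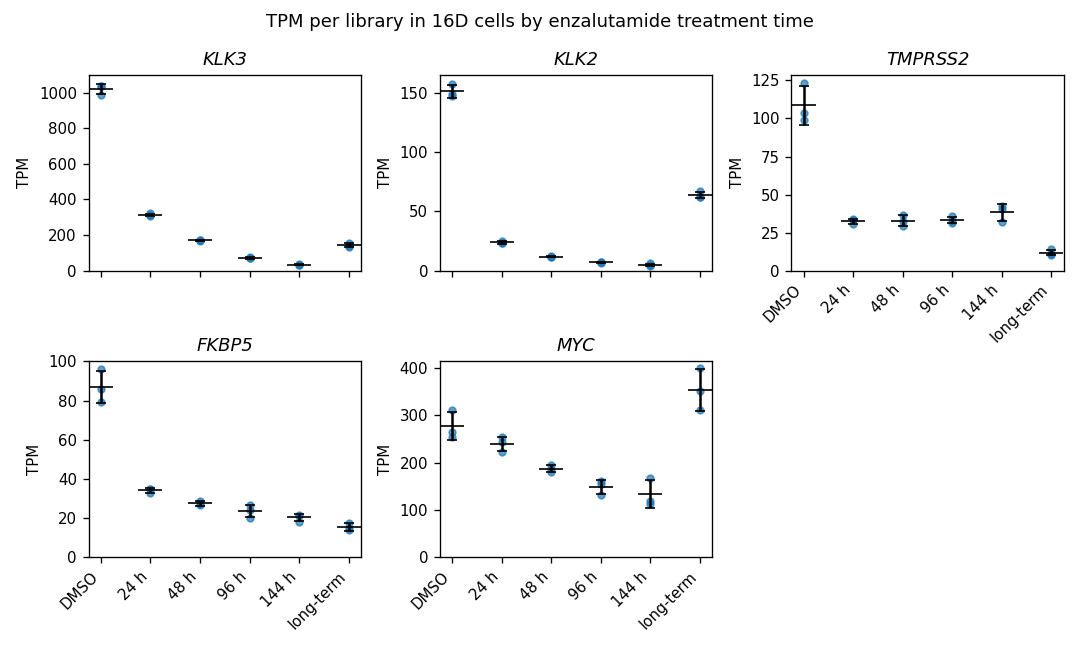
TPM of 5 genes in each library (points), with group means (bars) and SD (error bars, n = 3). KLK3 went from 1021 TPM in DMSO to 34.2 TPM at 144 h and 142 TPM long-term, while TMPRSS2 was at 38.4 TPM at 144 h and 11.9 TPM long-term.

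Of androgen-induced genes, 33 of 38 fell and 2 rose at 144 h, against 35 and 2 adjusted over the list alone (adjusted p = 2.59e-30, and adjusted p = 0.0459 with an estimated correlation). KLK4 was at -1.95. Glucocorticoid-response genes had 1 of 10 members higher and 7 lower, or 1 and 7 adjusted over the list alone (adjusted p = 1.31e-05, and adjusted p = 0.0459 with an estimated correlation). MT2A was at -1.27 and ZBTB16 at -1.56. Androgen-repressed genes had 7 of 9 members higher and 2 lower, or 7 and 2 adjusted over the list alone and a median of 2.03 (adjusted p = 0.00114, and adjusted p = 0.288 with an estimated correlation). UGT2B15 was at 3.04, UGT2B17 at 2.17 and OPRK1 at 2.47. MYC nucleolar targets had 0 of 42 members higher and 38 lower, or 0 and 38 adjusted over the list alone (adjusted p = 2.11e-20, and adjusted p = 0.0517 with an estimated correlation). NOP56 was at -0.90, SRM at -0.73 and PUS1 at -0.86. S phase genes had 0 of 41 members higher and 36 lower, or 0 and 36 adjusted over the list alone (adjusted p = 1.6e-15, and adjusted p = 0.238 with an estimated correlation). CDC45 was at -0.78 and CDC6 at -0.98. Genes of G2 and mitosis had 0 of 51 members higher and 34 lower, or 0 and 36 adjusted over the list alone (adjusted p = 8.14e-10, and adjusted p = 0.288 with an estimated correlation). AURKB, a mitotic kinase gene, was at -0.55, CKS1B at -0.55 and HMMR at -0.80.

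At 144 h, the fatty acid synthesis list had 3 of 17 members higher and 13 lower, or 3 and 13 adjusted over the list alone (adjusted p = 3.63e-07, and adjusted p = 0.288 with an estimated correlation). ACSL3 was at -2.52 and ELOVL5 at -2.03. Cholesterol synthesis had 1 of 23 members higher and 15 lower, or 1 and 16 adjusted over the list alone (adjusted p = 1.04e-06, and adjusted p = 0.288 with an estimated correlation). EBP was at -0.70. ATF4 targets had 1 of 23 members higher and 16 lower, or 1 and 17 adjusted over the list alone (adjusted p = 1.63e-08, and adjusted p = 0.238 with an estimated correlation). ASNS was at -0.90, SLC7A5 at -0.92 and PCK2 at -0.61. Neuroendocrine markers had 4 of 7 members higher and 0 lower, or 4 and 0 adjusted over the list alone (adjusted p = 0.0181, and adjusted p = 0.288 with an estimated correlation). ENO2 was at 2.33, SYT4 at 1.24 and SYP, synaptophysin, at 0.50. The WNT, NOTCH and hedgehog list had 7 of 14 members higher and 0 lower, or 7 and 0 adjusted over the list alone (adjusted p = 0.00750, and adjusted p = 0.288 with an estimated correlation). SOX9 was at 2.50, NOTCH3 at 2.46 and WNT5A at 1.96. Antigen presentation had 9 of 11 members higher and 1 lower, or 9 and 2 adjusted over the list alone (adjusted p = 0.00464, and adjusted p = 0.288 with an estimated correlation). TAPBP was at 1.16. Immediate early genes had 1 of 12 members higher and 7 lower, or 2 and 7 adjusted over the list alone (adjusted p = 0.00259, and adjusted p = 0.288 with an estimated correlation). FOS was at -1.47. Unfolded protein response genes had 1 of 22 members higher and 11 lower, or 1 and 11 adjusted over the list alone (adjusted p = 0.000472, and adjusted p = 0.405 with an estimated correlation). MANF was at -0.63. Autophagy and lysosome genes had 14 of 22 members higher and 0 lower, or 14 and 2 adjusted over the list alone (adjusted p = 0.00427, and adjusted p = 0.405 with an estimated correlation). MAP1LC3B was at 0.95. Replication-dependent histone genes had 10 of 12 members higher and 0 lower, or 10 and 0 adjusted over the list alone (adjusted p = 0.000283, and adjusted p = 0.159 with an estimated correlation). HIST2H2BE was at 1.24. In all 6941 genes changed at 144 h, 4294 higher and 2647 lower, and 898 by at least 1 on the log2 scale, 622 up and 276 down. Libraries did not overlap for 50.1% of genes, where chance gives 10%, and 20 lists were called. The higher share of the calls was 61.9%, against 46.8% after median-of-ratios scaling and 49.7% after quantile normalization.

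In the long-term culture, the androgen-induced genes stood at different distances below DMSO. KLK2 was at 63.7 ± 2.74 TPM (-1.23 ± 0.09 against DMSO) and KLK3 at 142 ± 12.4 TPM (-2.84 ± 0.06), whereas TMPRSS2 was at 11.9 ± 1.90 TPM (-3.09 ± 0.12) and FKBP5 at 15.3 ± 1.90 TPM (-2.43 ± 0.10). The largest increase was in PLPPR1 (ENSG00000148123, chromosome 9, 101028709 to 101325135), which rose from 0.1 ± 0.0985 to 92.6 ± 13 TPM. ADCYAP1, which encodes the neuropeptide PACAP, rose from 0.0267 ± 0.0252 to 57.8 ± 9.49 TPM, and the axon guidance receptor gene ROBO2 from 0.00330 ± 0.00580 to 46.2 ± 5.60 TPM. No untreated culture of the same age was held, so time in culture and treatment cannot be separated in this comparison, and the harvest time of the DMSO libraries is not stated.

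Other large increases in the long-term libraries were in LRATD1 (5.92), the adhesion receptor gene ADGRL3 (5.42), LRRTM4 (5.20), VSTM2A (5.09), the serotonin receptor gene HTR7 (5.05), IGFBP3 (4.97) and the pseudokinase gene TRIB2 (4.89). The largest decreases were in TMEFF2 (-7.47), ST6GALNAC1 (-6.94), RALYL (-6.68), UGT2B11 (-6.53), ELOVL7 (-5.19), the prostaglandin receptor gene PTGFR (-5.18), BCHE, butyrylcholinesterase (-5.12), ELOVL2 (-5.08), S100P (-4.97) and SLC44A4 (-4.96). RALYL went from 105 ± 6.59 to 0.0333 ± 0.0153 TPM. HK2 (-1.57), MKI67 (-0.68) and DNM1L (-0.60) fell, and CDKN1A had no call (adjusted p = 0.0860). MYC was at 353 ± 44.3 TPM (0.35 ± 0.13, adjusted p = 0.0324), and the adjusted p became 0.0910 without DMSO replicate 1, 0.111 without DMSO replicate 3, 0.136 without long-term replicate 2, 0.0682 without long-term replicate 3 and 0.0787 without a filter.

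Of androgen-induced genes, 32 of 38 were lower and 5 higher in the long-term libraries, against 32 and 5 adjusted over the list alone (adjusted p = 1.66e-13, and adjusted p = 0.234 with an estimated correlation). SLC45A3 was at -4.62. Androgen-repressed genes were not called as a list (adjusted p = 0.262). Fatty acid synthesis had 1 of 17 members higher and 14 lower, or 1 and 14 adjusted over the list alone (adjusted p = 9.06e-08, and adjusted p = 0.313 with an estimated correlation). SCD, the stearoyl-CoA desaturase gene, was at -3.24 and ACSL3 at -3.15. Cholesterol synthesis had 0 of 23 members higher and 20 lower, or 0 and 20 adjusted over the list alone (adjusted p = 5.26e-07, and adjusted p = 0.365 with an estimated correlation). FDFT1 was at -1.49. S phase genes had 0 of 41 members higher and 38 lower, or 0 and 39 adjusted over the list alone (adjusted p = 3.29e-11, and adjusted p = 0.313 with an estimated correlation). RRM2, a ribonucleotide reductase gene, was at -1.60, MCM7 at -1.01 and GMNN at -1.18. Genes of G2 and mitosis had 0 of 51 members higher and 42 lower, or 0 and 42 adjusted over the list alone (adjusted p = 3.3e-07, and adjusted p = 0.441 with an estimated correlation). NCAPD2 was at -0.97 and LBR at -1.69. MYC nucleolar targets had 1 of 42 members higher and 35 lower, or 2 and 35 adjusted over the list alone (adjusted p = 1.94e-06, and adjusted p = 0.313 with an estimated correlation). ODC1, ornithine decarboxylase, was at -1.54. Glucocorticoid-response genes had 1 of 10 members higher and 8 lower, or 1 and 8 adjusted over the list alone (adjusted p = 0.00309, and adjusted p = 0.234 with an estimated correlation). ZBTB16 was at -2.99 and the kinase gene SGK1 at 2.00. ATF4 targets had 1 of 23 members higher and 14 lower, or 1 and 14 adjusted over the list alone (adjusted p = 0.00734, and adjusted p = 0.578 with an estimated correlation). SLC7A5 was at -1.69 and, in the other direction, DDIT3 at 1.73.

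In the long-term libraries, the WNT, NOTCH and hedgehog list had 8 of 14 members higher and 4 lower, or 8 and 4 adjusted over the list alone (adjusted p = 0.00309, and adjusted p = 0.313 with an estimated correlation). SOX9 was at 3.45, LEF1 at 2.77 and HES1 at 2.20. Neuroendocrine markers had 4 of 7 members higher and 1 lower, or 4 and 1 adjusted over the list alone (adjusted p = 0.00931, and adjusted p = 0.313 with an estimated correlation). ENO2 was at 2.83, SYT4 at 2.70 and NTS, neurotensin, at 1.73. The p53 and arrest list had 8 of 21 members higher and 4 lower, or 8 and 4 adjusted over the list alone (adjusted p = 0.0124, and adjusted p = 0.578 with an estimated correlation). BTG2 was at 2.14, SESN1 at 1.71 and CDKN2B, the p15 gene, at 1.49. Antigen presentation had 7 of 11 members higher and 2 lower, or 8 and 2 adjusted over the list alone (adjusted p = 0.00309, and adjusted p = 0.313 with an estimated correlation). B2M, in the other direction, was at -0.94. Autophagy and lysosome genes had 10 of 22 members higher and 4 lower, or 12 and 4 adjusted over the list alone (adjusted p = 0.00966, and adjusted p = 0.578 with an estimated correlation). SQSTM1 was at 0.84. Replication-dependent histone genes had 11 of 12 members higher and 0 lower, or 11 and 0 adjusted over the list alone (adjusted p = 7.25e-05, and adjusted p = 0.234 with an estimated correlation). HIST1H4H was at 0.86. Genes of respiration encoded by mitochondrial DNA had 6 of 13 members higher and 0 lower, or 6 and 0 adjusted over the list alone (adjusted p = 0.00429, and adjusted p = 0.578 with an estimated correlation). The adjusted p was 0.718 after quantile normalization. With the mitochondrial share as a covariate the direction turned to lower, with adjusted p = 0.0376. That share contains the TPM of these same genes, so the covariate cannot test their rise. The mitochondrial share of TPM was 26.4% in these libraries and 19.4% in DMSO, and mitochondrial ribosomal RNA took 5.21% against 2.59%. In all 8413 genes changed, 2931 higher and 5482 lower, and 1546 by at least 1 on the log2 scale, 714 up and 832 down. Libraries did not overlap for 57.4% of genes, where chance gives 10%, and 17 lists were called. The median log2 fold change over all genes was -0.12, and scaling moved it by 0.11 (median-of-ratios, quantile, or without mitochondrial genes) and the mitochondrial share as a covariate by 0.12. The higher share of the calls was 34.8%, against 47.6% with median-of-ratios scaling, 48.7% with quantile normalization, 48.1% without mitochondrial genes and 49.9% with the mitochondrial share as a covariate.

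**Figure D3:**
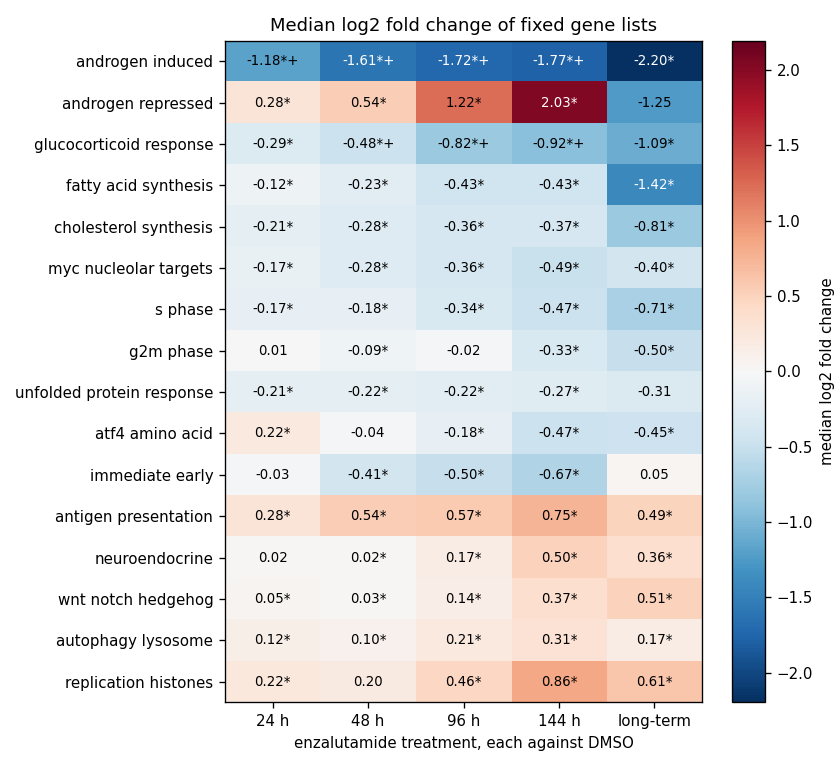
Median log2 fold change of the members of 16 gene lists in each treated group against DMSO. A star marks camera adjusted p under 0.05 and a plus sign the same with an estimated correlation; the androgen-induced median was -1.18 at 24 h and -1.77 at 144 h.

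Between 24 h and 144 h of treatment, the comparison shows what differed between these times, to which drug and time in culture may both contribute. KLK3 fell further, from 313 ± 7.22 to 34.2 ± 1.95 TPM (-3.16 ± 0.06, adjusted p = 7.21e-15), and KLK2 from 23.8 ± 1.06 to 4.99 ± 1.01 TPM (-2.06 ± 0.09), whereas TMPRSS2 (0.22 ± 0.12, adjusted p = 0.180) had no call. MYC fell from 240 ± 15.2 to 133 ± 29.4 TPM (-0.87 ± 0.13, adjusted p = 9.52e-05). MAST4 (3.06), CNTN5 (2.98), IGFBP3 (2.98) and MATN2 (2.81) had the largest increases. TMEFF2 (-3.54), S100P (-3.32) and ST6GALNAC1 (-3.04) were among the largest decreases, and MIR4690 was listed at 0 in all 24 h libraries and at 6.43 TPM at 144 h. MIR4690 is a small RNA gene and no read counts were held, so few reads may underlie its values. SCGB1A1 went from 7.42 ± 2.28 TPM to a level listed at 0. FKBP5 (-0.72) and HK2 (-1.05) fell, and DNM1L, MKI67 and CDKN1A had adjusted p of 0.635, 0.0648 and 0.0824.

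Between 24 h and 144 h, ATF4 targets had 0 of 23 members higher and 20 lower, or 0 and 20 adjusted over the list alone (adjusted p = 2.7e-20, and adjusted p = 0.0760 with an estimated correlation). ASNS was at -1.15, SLC7A5 at -1.59 and CHAC1 at -1.27. MYC nucleolar targets had 0 of 42 members higher and 31 lower, or 0 and 35 adjusted over the list alone (adjusted p = 2.7e-20, and adjusted p = 0.0760 with an estimated correlation). GNL3, nucleostemin, was at -0.44. Genes of G2 and mitosis had 0 of 51 members higher and 35 lower, or 0 and 38 adjusted over the list alone (adjusted p = 5.03e-16, and adjusted p = 0.158 with an estimated correlation). CCNB1, cyclin B1, was at -0.50. S phase genes had 0 of 41 members higher and 21 lower, or 1 and 29 adjusted over the list alone (adjusted p = 8.67e-12, and adjusted p = 0.274 with an estimated correlation). CDC45 was at -0.61. Androgen-induced genes had 2 of 38 members higher and 24 lower, or 3 and 25 adjusted over the list alone (adjusted p = 5.16e-13, and adjusted p = 0.158 with an estimated correlation). KLK4 was at -0.99. Androgen-repressed genes had 7 of 9 members higher and 2 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.000572, and adjusted p = 0.281 with an estimated correlation). UGT2B17 was at 2.14. Fatty acid synthesis had 3 of 17 members higher and 11 lower, or 3 and 11 adjusted over the list alone (adjusted p = 1.41e-06, and adjusted p = 0.281 with an estimated correlation). ME1, malic enzyme, was at -1.08. Immediate early genes had 0 of 12 members higher and 8 lower, or 0 and 8 adjusted over the list alone (adjusted p = 2.61e-05, and adjusted p = 0.158 with an estimated correlation). FOSB was at -1.58. Glucocorticoid-response genes had 1 of 10 members higher and 6 lower, or 1 and 6 adjusted over the list alone (adjusted p = 0.000682, and adjusted p = 0.129 with an estimated correlation). MT2A was at -1.84. Neuroendocrine markers had 4 of 7 members higher and 0 lower, or 4 and 0 adjusted over the list alone (adjusted p = 0.00458, and adjusted p = 0.158 with an estimated correlation). DDC was at 2.59. In all 4802 genes changed, 3001 higher and 1801 lower, and 386 by at least 1 on the log2 scale, 271 up and 115 down. Libraries did not overlap for 40.4% of genes, where chance gives 10%, and 19 lists were called. The higher share of the calls was 62.5%, against 47.4% with median-of-ratios scaling and 49.4% with quantile normalization.

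Between 144 h and long-term treatment, KLK2 rose from 4.99 ± 1.01 to 63.7 ± 2.74 TPM (3.45 ± 0.09, adjusted p = 4.52e-14) and KLK3 from 34.2 ± 1.95 to 142 ± 12.4 TPM (2.02 ± 0.06), while TMPRSS2 fell from 38.4 ± 5.42 to 11.9 ± 1.90 TPM (-1.61 ± 0.12, adjusted p = 2.04e-08). MYC rose from 133 ± 29.4 to 353 ± 44.3 TPM (1.42 ± 0.13, adjusted p = 2.25e-07), and the median of its 30 nearest neighbours among genes with a mean of at least 5 TPM, centred on the median of all such genes, was 0.37. The largest increases were in PLPPR1 (6.21), ADCYAP1 (5.86), ROBO2 (5.32), ADGRL3 (5.21) and HTR7 (4.93). The largest decreases were in UGT2B15, from 208 ± 12.9 to 0.320 ± 0.102 TPM, UGT2B17, from 114 ± 7.98 to 0.227 ± 0.0643 TPM, RALYL (-6.84), BCHE (-6.44) and SLC44A4 (-5.60).

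The calls of 3 smaller differences between 144 h and long-term ended under some alternatives. FKBP5 was at -0.39, with adjusted p = 0.00593, which became 0.0621 after median-of-ratios scaling, 0.0589 after quantile normalization and 0.308 with the mitochondrial share as a covariate. DNM1L was at -0.32 (adjusted p = 0.0117), with 0.0572 without 144 h replicate 3, 0.0522 without long-term replicate 3, 0.360 after median-of-ratios scaling, 0.199 after quantile normalization, 0.0532 without mitochondrial genes and 0.310 with the mitochondrial share as a covariate. CDKN1A was at 0.39 (adjusted p = 0.00469), which became 0.0555 in a fit of only those 6 libraries. HK2 and MKI67 had no call (adjusted p = 0.110 and 0.0796).

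Of the 38 androgen-induced genes, 11 were higher and 18 lower in the long-term libraries than at 144 h, against 11 and 19 adjusted over the list alone, with a list adjusted p = 0.265. The list's median was -0.22 while the direction of its test was up. Androgen-repressed genes had 2 of 9 members higher and 7 lower, or 2 and 7 adjusted over the list alone (adjusted p = 0.000296, and adjusted p = 0.811 with an estimated correlation). ACKR3 was at -3.28. MYC nucleolar targets had 15 of 42 members higher and 2 lower, or 15 and 2 adjusted over the list alone (adjusted p = 1.72e-05, and adjusted p = 0.811 with an estimated correlation). NOP16 was at 0.58 and IMP4 at 0.46. Fatty acid synthesis had 0 of 17 members higher and 13 lower, or 0 and 15 adjusted over the list alone (adjusted p = 1.72e-05, and adjusted p = 0.811 with an estimated correlation). SCD was at -2.43 and ACACA, acetyl-CoA carboxylase, at -1.04. Cholesterol synthesis had 1 of 23 members higher and 19 lower, or 1 and 19 adjusted over the list alone (adjusted p = 0.00288, and adjusted p = 0.811 with an estimated correlation). STARD4 was at -1.81 and INSIG1 at -1.07. ATF4 targets had 8 of 23 members higher and 5 lower, or 8 and 6 adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.811 with an estimated correlation). ATF4 was at 0.40 and PHGDH at -0.83. Glycolysis had 7 of 23 members higher and 2 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.00288, and adjusted p = 0.811 with an estimated correlation). LDHB was at 1.07 and PFKP at 1.09, and the list's median of -0.01 was opposite in sign to the direction of its test. In all 7450 genes changed, 1493 higher and 5957 lower, and 974 by at least 1 on the log2 scale, 289 up and 685 down. Libraries did not overlap for 47.8% of genes, where chance gives 10%, and 11 lists were called. The median log2 fold change over all genes was -0.19, and median-of-ratios scaling moved it by 0.20, quantile normalization by 0.19, leaving out mitochondrial genes by 0.10 and the covariate by 0.12. The higher share of the calls was 20.04%, against 52.0% with median-of-ratios scaling, 48.6% with quantile normalization, 35.1% without mitochondrial genes and 37.6% with the covariate.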

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

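The weighing of the androgen-induced genes used tests that were chosen only after the result was seen. The values here are differences of effects between treatment times, each tested directly as a comparison of the treated groups, for 9 tested genes named in every comparison and for the gene lists. For lists the camera test asks whether the members changed otherwise than the other genes, so a called list need not itself have changed. Restricting the part to these was also decided after the results were seen. Of the other 212 named genes, 165 differed between 144 h and 24 h and 144 between long-term and 144 h. Those 212 genes were named for large changes or small adjusted p, including in these same comparisons. Their counts therefore do not measure how common such differences were. Of all genes tested, 29.7% changed between 144 h and 24 h and 46.1% between long-term and 144 h.

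The effect against DMSO at 144 h minus that at 24 h differed from 0 for 5 of the tested genes named in every comparison. It was -3.16 for KLK3, -2.06 for KLK2, -0.72 for FKBP5, -0.87 for MYC and -1.05 for HK2 on the log2 scale. Of the lists, 19 stood apart from the other genes with the preset correlation and 0 with an estimated one. The median differences of lists that went down were -0.50 for androgen-induced genes, -0.50 for glucocorticoid response, -0.36 for MYC nucleolar targets, -0.13 for glycolysis, -0.11 for nuclear genes of oxidative phosphorylation, -0.16 for cholesterol synthesis, -0.51 for fatty acid synthesis, -0.27 for S phase, -0.35 for G2 and mitosis, -0.68 for ATF4 targets, -0.50 for immediate early genes and -0.12 for ribosomal proteins. Those of lists that went up were 0.89 for androgen-repressed genes, 0.16 for fatty acid oxidation, 0.52 for antigen presentation, 0.48 for neuroendocrine markers, 0.29 for WNT, NOTCH and hedgehog, 0.27 for autophagy and lysosome and 0.50 for replication-dependent histones. Some of these calls ended under alternatives. For glycolysis the adjusted p was 0.0890 with a filter of 5 TPM, 0.0954 after quantile normalization, 0.0606 without a variance trend, 0.0621 and 0.1004 without 24 h replicates 1 and 2, and 0.162 without 144 h replicate 2. It was 0.197 after quantile normalization for nuclear oxidative phosphorylation. For fatty acid oxidation it was 0.0815 after median-of-ratios scaling, 0.0564 without a variance trend and 0.0880 without 144 h replicate 3.

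The long-term effect minus that at 144 h differed from 0 for 7 of these genes. It was 2.02 for KLK3, 3.45 for KLK2, -1.61 for TMPRSS2 and 1.42 for MYC. For DNM1L it was -0.32, with adjusted p of 0.0572 without 144 h replicate 3 and 0.0522 without long-term replicate 3, 0.360 after median-of-ratios scaling, 0.199 after quantile normalization, 0.0532 without mitochondrial genes and 0.310 with the mitochondrial share as a covariate. It was -0.39 for FKBP5, with 0.0621 after median-of-ratios scaling, 0.0589 after quantile normalization and 0.308 with the covariate, and 0.39 for CDKN1A. Of the lists, 11 stood apart from the other genes with the preset correlation and 0 with an estimated one. The median differences were -1.80 for androgen-repressed genes, 0.08 for MYC nucleolar targets, -0.01 for glycolysis, -0.01 for nuclear genes of oxidative phosphorylation, 0.35 for mitochondrially encoded genes of oxidative phosphorylation, -0.43 for cholesterol synthesis, -0.85 for fatty acid synthesis, 0.04 for ATF4 targets, 0.21 for hypoxia, 0.31 for EMT and 0.07 for ribosomal proteins. The mitochondrially encoded list had adjusted p of 0.822 after quantile normalization, and 0.0969 in the other direction with the mitochondrial share as a covariate. That covariate contains the TPM of the list's own genes, so it cannot test their rise. EMT had 0.131 after median-of-ratios scaling, 0.0904 after quantile normalization and 0.0793 with the covariate. Hypoxia had 0.0504 and 0.0566 with those 2 scalings and 0.0537 without 144 h replicate 2. Nuclear oxidative phosphorylation had 0.0520 without 144 h replicate 1, and ribosomal proteins 0.0563 after quantile normalization. For glycolysis and nuclear oxidative phosphorylation the test's direction was up although the median was below 0. Both medians lay above that of all genes tested, which was -0.19 in TPM and 0.01 with median-of-ratios scaling. TPM are relative, so a rise of these lists and a fall of the other genes cannot be told apart.

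Of the 33 androgen-induced genes lower at 144 h than in DMSO, 9 were higher in the long-term libraries than at 144 h, 15 were lower and 9 had no call. A carry-over of untreated cells that kept DMSO levels would bring all their abundant transcripts. The smallest untreated share that the rising genes would need was 8.15%, the largest 240.4%. Of 3332 genes with at least 50 TPM in DMSO, 16 lay below the level of that smallest share in each long-term library. That argues against cells with DMSO levels as the source of the rise. Cells regrowing under the drug need not keep those levels, so these values do not test regrowth. Rescaling without the mitochondrially encoded genes moved the median log2 fold change of all genes by 0.10. Members had changed by as much as 3.45 (KLK2) and -1.61 (TMPRSS2), so both directions were bound to stay after rescaling. After it 12 members were higher and 14 lower, which is no separate test. A common shift of that size is too small for changes such as those of KLK2 and TMPRSS2. A different response of single genes to long treatment, the age of the culture and selection of a subline remain open and may each contribute, since no untreated culture of the same age was held.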

How the results depend on the processing

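The covariate of the mitochondrial share was chosen only after the data were seen. The number of genes changed at 24 h against DMSO was 1321 and became 2026 with median-of-ratios scaling, 2292 with the mitochondrial share as a covariate and 869 to 1006 without single libraries, the lowest without DMSO replicate 1; the cause was not tested, except that leaving out a library leaves fewer samples. In the other 6 comparisons each alternative gave a count within 1.5 times the main one. With the replicate number as a block the counts were 1210, 2650, 4588, 6829, 8308, 4663 and 7312, in the order 24, 48, 96 and 144 h and long-term against DMSO, 144 h against 24 h and long-term against 144 h. The replicate numbers did not pair the libraries: deviations from the group mean correlated across genes with a mean r of 0.005 for the same number, and 4 of 18 libraries correlated best with a library of their own number.

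The gene lists called with an estimated correlation were 1 at 24 h (14 with the preset one), 2 at 48 h (16), 2 at 96 h (16), 2 at 144 h (20), 0 for long-term (17), 0 for 144 h against 24 h (19) and 0 for long-term against 144 h (11), where quantile normalization gave 7. The larger correlation allowed between genes is how that test differs; the cause of the 7 was not tested. For lists a direction was read only where the list was called in the main or the alternative setting, a limit set after the results were seen, and in 75 further list results called in neither setting the direction differed.

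Directions that reversed were these, and the causes were not tested, apart from 1 that the design gives and that is stated below. With fry, which compares a list with no other genes, adjusted p were 0.00977 for EMT at 96 h, 0.0292 for steroid synthesis long-term against DMSO, and 0.0220 for autophagy and lysosome and 0.0326 for replication-dependent histones long-term against 144 h. With quantile normalization the adjusted p was 0.884 for nuclear oxidative phosphorylation at 144 h, and the log2 fold change was 0.012 for HK2 long-term against 144 h. With the mitochondrial share as a covariate, adjusted p for the mitochondrially encoded list were 0.0376 long-term against DMSO and 0.0969 against 144 h, and log2 fold changes were -0.0138 and -0.0244 for MT-CO2 and 0.0605 for HK2 against 144 h. The covariate contains the TPM of MT-CO2 and of that list's genes, so the loss of their rise is built into that fit. Without single libraries, values with no call ran from -0.1325 to 0.0363 for MKI67 and from -0.0063 to 0.1075 for CDKN1A at 24 h.

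Of 544 results for named genes, leaving out single libraries ended 31 calls and added 7. Calls ended and added were 5 and 9 with median-of-ratios scaling, 9 and 6 with quantile normalization, 1 and 5 of 536 without mitochondrial genes, 8 and 5 with the covariate, 15 and 0 without a filter, 12 and 2 in fits of only 2 groups, 4 and 0 with a pseudocount of 0.1, 2 and 0 without a variance trend, 4 and 0 with the block, and 0 and 1 of 533 with a filter of 5 TPM. Depth is unknown, so no limit from counting can be given.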

Other observations

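Of the tests here, those of disjoint library pairs, of the rescaled shares and of other splits of the libraries were chosen only after the result was seen. Several gene lists had no call by camera in any comparison with DMSO, and the adjusted p in brackets are from that test. Interferon-response genes had 10 of 20 members higher and 0 lower, or 12 and 2 adjusted over the list alone at 144 h (adjusted p = 0.0699). Glycolysis had 4 of 23 members higher and 10 lower, or 4 and 10 adjusted over the list alone at 144 h (adjusted p = 0.0647), and the citric acid cycle 2 of 18 members higher and 6 lower, or 2 and 6 adjusted over the list alone (adjusted p = 0.0683). In the long-term libraries, luminal prostate genes had 4 of 15 members higher and 9 lower, or 4 and 9 adjusted over the list alone (adjusted p = 0.305), EMT genes 5 of 9 members higher and 3 lower, or 5 and 3 adjusted over the list alone (adjusted p = 0.262), hypoxia-response genes 5 of 13 members higher and 2 lower, or 5 and 3 adjusted over the list alone (adjusted p = 0.240) and steroid synthesis genes 2 of 8 members higher and 4 lower, or 2 and 4 adjusted over the list alone (adjusted p = 0.988). Limma's fry, which does not compare a list with other genes, called interferon-response genes higher and EMT genes lower at 24, 48, 96 and 144 h. It called luminal prostate genes lower at 24, 48 and 96 h and long-term, and steroid synthesis genes higher long-term (adjusted p = 0.0292). Among the markers of other cell types, COL1A1 went from 14.5 TPM in DMSO to 29.4 TPM at 144 h and 7.25 TPM long-term, the integrin gene ITGA6 from 14.8 TPM in DMSO to 3.23 TPM long-term, and ITGB4 from 2.56 TPM in DMSO to 14.2 TPM at 144 h and 10.8 TPM long-term; these values were not tested as a list.

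Differences of the long-term culture from DMSO along the chromosomes were examined in 343 windows of 30 neighbouring genes with a mean of at least 5 TPM, and 14 windows lay beyond the permutation threshold, against 2 at 144 h, which a copy number or regional change would give. After removing GC content and transcript length trends, 8 of the 14 stayed, barely more than the 7 or more that counted against that cause. That argues against these trends as the whole cause. With the mitochondrial share as a covariate 11 stayed. Window medians were centred on the median of these genes, so a common shift could hardly make or remove a window. The 11 therefore do not test whether that share set the scale of the other genes. Local noise in single libraries stays open. A test chosen beforehand counted for noise if any of 18 contrasts of 1 library with the others of its group gave at least 14 windows. That condition was met by the 20 windows of 144 h replicate 3, so the test came out for noise. This library is outside the comparison, and 2 of its 20 windows were among the 14. In all, 13 of the 18 contrasts gave at least 1 window. None of the 6 libraries compared gave more than 2. In 3 disjoint pairs of 1 long-term and 1 DMSO library, 8 windows lay beyond the threshold in the same direction in all pairs, and 0 at each of 24, 48, 96 and 144 h, which argues against library noise as the whole cause. A copy number difference, a regional change, the age of the culture or another subline may underlie these windows, and no genotype was tested.

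The 8 windows found in all 3 pairs, of which 7 were also beyond the threshold after the GC and length correction, were on chromosome 2, from 217730 to 10837977, 47345158 to 61888804 and 61888724 to 70281191, and on chromosome 8, from 232137 to 18223689, 19313617 to 25507920 (not beyond it after that correction), 26291491 to 37700021, 37736601 to 43202855 and 96239398 to 103073051 (GRCh38). The last was higher in the long-term libraries and the other 7 lower. Between 144 h and long-term 13 windows lay beyond the threshold, and 1 of them, on chromosome 8 from 124450820 to 142736927, contains MYC, with a median of 0.45 and 1 of 30 genes below the median of all genes in the windows' analysis. Replicates 2 and 3 of the 144 h group gave 13 and 20 windows against the others of their group. Library noise therefore stays open for these 13 windows, and pairs of long-term and 144 h libraries were not examined. Against DMSO the window that contains MYC was not among the 14 but lay beyond the threshold after the GC and length correction, at 0.41. The centred log2 fold change of MYC, long-term against 144 h, was 1.63, and the median of its 30 neighbours was 0.37, with 26 of 30 above 0.

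More genes were called lower than higher in the long-term libraries, with 34.8% higher against DMSO and 20.04% higher against 144 h. Rescaling without the mitochondrially encoded genes gave 48.1% higher against DMSO, so the larger mitochondrial share of TPM is a candidate explanation for that excess. Against 144 h the same rescaling gave 35.1%, so that share is not the whole cause there.

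For each comparison the 6 libraries can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05, the smallest being 0.1. The real split was the only 1 of 10 with as many genes called. Every other split mixes libraries of both groups, so a difference between the groups enters its spread and lowers its calls. The counts of the other splits are therefore no measure of what chance alone gives. At 24 h it called 1321 genes and the highest other split 1, at 48 h 2823 and 1, at 96 h 4729 and 1, at 144 h 6941 and 0, long-term against DMSO 8413 and 2, at 144 h against 24 h 4802 and 1, and long-term against 144 h 7450 and 1.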
